A study of Mus musculus with 4 samples.

How the data were processed

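Droplet 3′ single-cell RNA sequencing (Chromium v2 chemistry, Illumina HiSeq) had been run on cells of adult mouse back skin in 4 libraries of 1 replicate each: control untreated, control imiquimod, Ovol1 null untreated and Ovol1 null imiquimod. Per the labels, 10000 cells per library and about 50000 reads per cell had been aimed at. The deposited matrix holds UMI counts, as whole numbers, for 27998 genes in 23455 barcodes. Per the submitters' processing notes the counts came from Cell Ranger 2.1.0 and genome build mm10, and per the labels the 4 libraries had been combined with the aggr step, each barcode carrying a suffix for its library. Whether that step had thinned reads to a common depth, and which annotation release had been used, is not given in the sources used here. Totals and UMIs per cell differed between libraries. The gene table supplied names only.

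Barcodes with at least 200 detected genes and at most 10% mitochondrial UMIs were kept. Doublets were called per library with Scrublet at an expected rate of 0.05 and left out, which removed 126, 89, 73 and 107 cells (2.04%, 1.57%, 1.38% and 1.89% of those that passed) in the order above. The filter had removed 116, 192, 272 and 56 barcodes. Counts were scaled to 10000 per cell and log-transformed. Then 2000 variable genes, 30 principal components, 15 neighbours and the Leiden method at resolution 1 gave 30 clusters over all libraries together, without batch correction. Clusters were named by lists of markers for 22 cell types. A marker counted when it was at least 2-fold above the other clusters, with 10 CPM added, and seen in at least 10% of the cluster's cells, and a name needed at least 3 markers. Clusters of the same name formed a class. The joint clustering left 3 clusters without a name, 1 of them with 1008 cells that were nearly all from the library labelled Ovol1 null imiquimod. Cells of unnamed clusters took the name they had in a clustering of their own library. This filled 30, 24, 6 and 1228 cells, of which 749 basal, 210 suprabasal and 31 upper hair follicle keratinocytes, 237 fibroblasts and 1 neutrophil in the last library. The 30 cells of control untreated became fibroblasts by 3 of 8 markers, but their cluster was led by Rgs1, Ccl9 and Tyrobp, genes of immune cells. This source of class names, and which lists are spoken of in which class, were chosen after the data had been seen and other schemes had been looked at. The markers Krt85, Trbc2, Trdc, Trdv4 and Ighm and the list genes Selenop and Krt85 were not in the gene table under those symbols.

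UMIs were summed per class and library and scaled to the class total as CPM. A class was compared only with at least 50 cells in each library. The ratio of CPM was given with its exact conditional binomial 95% interval and CPM with an exact Poisson interval. Shares of cells had exact Clopper-Pearson intervals. All of these cover counting error only. Where a gene had 0 UMIs in one library, its ratio was given as a bound against 3 counts. For log2 ratios in list medians 0.5 count was added. With 1 library per group there was no test of a difference between groups, no p-value and no count of changed genes, since cells of one library are not replicates. The 4 comparisons were imiquimod against untreated within each genotype label and labelled null against control within each treatment. For the difference of both imiquimod effects, intervals came from 2000 gamma draws of the counts.

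Outside the sex-linked and haemoglobin lists 349 genes were read, and with those there were 30 lists. These were activation keratins, alarmins and antimicrobial proteins, IL-1 family, neutrophil-attracting chemokines, other chemokines, interferon-stimulated genes, type 17 lymphocyte genes, cornified envelope, differentiation keratins, barrier lipid synthesis, tight and adherens junctions and desmosomes, basement membrane adhesion, S phase, G2 and M phase, mesenchymal transition, Ovol family and Myc and Id genes, Nrf2 targets, aryl hydrocarbon receptor targets, hypoxia and glycolysis, cholesterol synthesis, fibroblast matrix, fibroblast inflammatory, inflammatory monocyte and macrophage, resident macrophage, MHC class II, endothelial adhesion, hair growth (anagen), immediate early and dissociation, sex-linked and haemoglobin. A member was measured with at least 20 UMIs over both libraries, and counted as higher or lower at a ratio of at least 1.5 with a counting interval on one side of 1. A list's median log2 ratio was set against those of 10000 random lists of the same size matched in 25 bins of expression. The sex-linked and haemoglobin lists are given by values. Some list genes were also markers that named the classes. Krt5, Krt14, Krt15, Itga6, Itgb4, Col17a1 and Lamb3 of basement membrane adhesion are basal markers. Krt1, Krt10, Krt77, Lor, Flg2, Krtdap, Sbsn, Dsc1 and Dsg1a of other lists are suprabasal markers. Ratios of these genes in keratinocytes were not separated from where the line between classes fell.

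Genes were named by a rule in 3 parts. The first took, in each comparison and in basal keratinocytes, suprabasal keratinocytes, fibroblasts and macrophages or monocytes, the 3 largest increases and 3 largest decreases by the interval bound nearest to 1. It drew on genes with at least 50 UMIs over both libraries, UMIs in at least 10% of cells in the library with the higher CPM and, against free RNA, a CPM of at least 1 in 10 of the highest in any class. Sex-linked list genes, mitochondrial genes and unnamed gene models were left out. The second took up to 4 measured members of each list spoken of, by the same bound. The third always allowed Ovol1, Ovol2, Krt6a, Krt6b, Krt16, Krt17, S100a8, S100a9, Lcn2, Il1a, Il1b, Il1rn, Cxcl1, Cxcl2, Cxcl3, Flg, Flg2, Lor, Ivl, Cldn1, Mki67 and Xist. The groups, comparisons, filters, markers, lists, this rule and 12 alternatives were fixed before the data were examined, and 2 alternatives (joint clusters alone and cells with at least 3100 UMIs) were added afterwards.

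The alternatives fixed in advance were a filter of 500 genes and 5% mitochondrial UMIs, called doublets kept, Leiden resolutions of 0.5 and 2, each library clustered on its own, the mean over cells of each cell's CPM, TMM factors, cells thinned to 1000 UMIs, list members with at least 100 UMIs, 5 counts added, shares among cells with at least 1000 UMIs, and the Ovol1 share after thinning. The method was tested on simulated data in which known ratios had been set. Counts were drawn from Poisson distributions, for which the intervals are made, so coverage near 95% was set by design. The simulation held no variation between cells, mice or preparations, so its rates of calls do not cover these. Intervals of unchanged genes held the true value for 95.3% to 96.6% of genes, and between 1.10% and 3.08% of unchanged genes were counted as higher or lower. All genes set 4-fold higher were called, and of those set 1.5-fold higher between 12.5% and 60%. Of genes set 4-fold lower between 76.5% and 100% were called, and of those set 2-fold lower between 55.3% and 100%, the lowest in macrophages. Of 100 unchanged lists of 12 genes, 5 fell outside the central 95% of random lists. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9, umap-learn 0.5.12, scikit-learn 1.9.0 and matplotlib 3.10.9, and edgeR 4.0.16 for TMM factors alone. The ratio of 1 gene is not reported here.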

Results

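Single-cell RNA sequencing had been run on adult mouse back skin (CD1 strain, 7 to 8 weeks old) in 4 droplet libraries, 1 per group. The groups were control and Ovol1 null, each untreated or treated with imiquimod, a Toll-like receptor agonist that brings on psoriasis-like inflammation when it is rubbed on skin. Per the labels, 62.5 mg of 5% cream had been given in one dose on shaved backs, and cells had been sorted by FACS before capture. With 1 library per group no test between groups was possible and cells were not counted as replicates. The intervals given are 95% intervals for counting error only. They leave out the variation between mice and between cell preparations, so each difference is one between single libraries.

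The control untreated library held 6302 barcodes, the control imiquimod library 5862, the library labelled Ovol1 null untreated 5564 and the library labelled Ovol1 null imiquimod 5727. After filtering, 6060, 5581, 5219 and 5564 cells remained in that order, with 37278167, 29706480.0, 31563084 and 55240722 UMIs. Median UMIs per cell were 5704.5, 4760, 5706 and 8395.5, and median detected genes 1760.5, 1530.0, 1727 and 2206. The lowest UMI count of a kept cell was 3039 in the library labelled Ovol1 null imiquimod and between 1413 and 1456 in the others. Cells under 3100 UMIs made up 0.341% of that library and 17.8%, 23.2% and 17.1% of the control untreated, control imiquimod and labelled-null untreated libraries. Of the sex-linked list, Xist, the RNA that silences an X chromosome, stood at 1251, 1295, 1579 and 689 CPM, counts scaled to the total, in the order above. The Y-linked genes had 2, 3, 1 and 0 UMIs.

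Keratinocytes and fibroblasts made up most cells. Epithelial classes together held 33.0% (31.8 to 34.2) of kept cells in the control untreated library, 51.8% (50.5 to 53.1) in control imiquimod, 53.7% (52.3 to 55.0) in labelled-null untreated and 30.9% (29.6 to 32.1) in labelled-null imiquimod, by exact Clopper-Pearson intervals. Fibroblasts held 54.4%, 42.1%, 37.4% and 56.6%. Basal keratinocytes numbered 990, 1550, 1320 and 871 cells and suprabasal keratinocytes 487, 760, 825 and 273. Macrophages or monocytes numbered 209, 83, 111 and 63 cells, and T or NK cells 288, 75, 169 and 172. Langerhans-like cells held 0.149%, 0.233%, 0.115% and 1.65%. These shares also carry the sort, the capture and the library-specific UMI minimum, so none was read as a share of the tissue. The same class often sat in different clusters in different libraries. Fibroblasts of both untreated libraries filled clusters 0, 1, 5 and 6, those of control imiquimod cluster 28 and those of labelled-null imiquimod cluster 26. Suprabasal cells of the untreated libraries filled cluster 8 and those of control imiquimod cluster 19, while the matching basal clusters were 14 and 25. Basal clusters 10, 16 and 17 were shared, with 384, 106 and 169 cells of control imiquimod beside cells of both untreated libraries. Cluster 10 had Sostdc1 and Defb6, of the upper hair follicle marker list, among its top genes. It gave 340, 384, 410 and 82 of the basal cells in the order above. With control imiquimod and labelled-null untreated clustered on their own, clusters led by Sostdc1 were named upper hair follicle keratinocytes. Basal ratios with labelled-null imiquimod were not separated from this difference in make-up. Most keratinocytes of the labelled-null imiquimod library came from cluster 3, which had no class name in the joint clustering. Of its 1008 cells, 991 were from that library, and they were named in a clustering of that library alone.

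**Figure D1:**
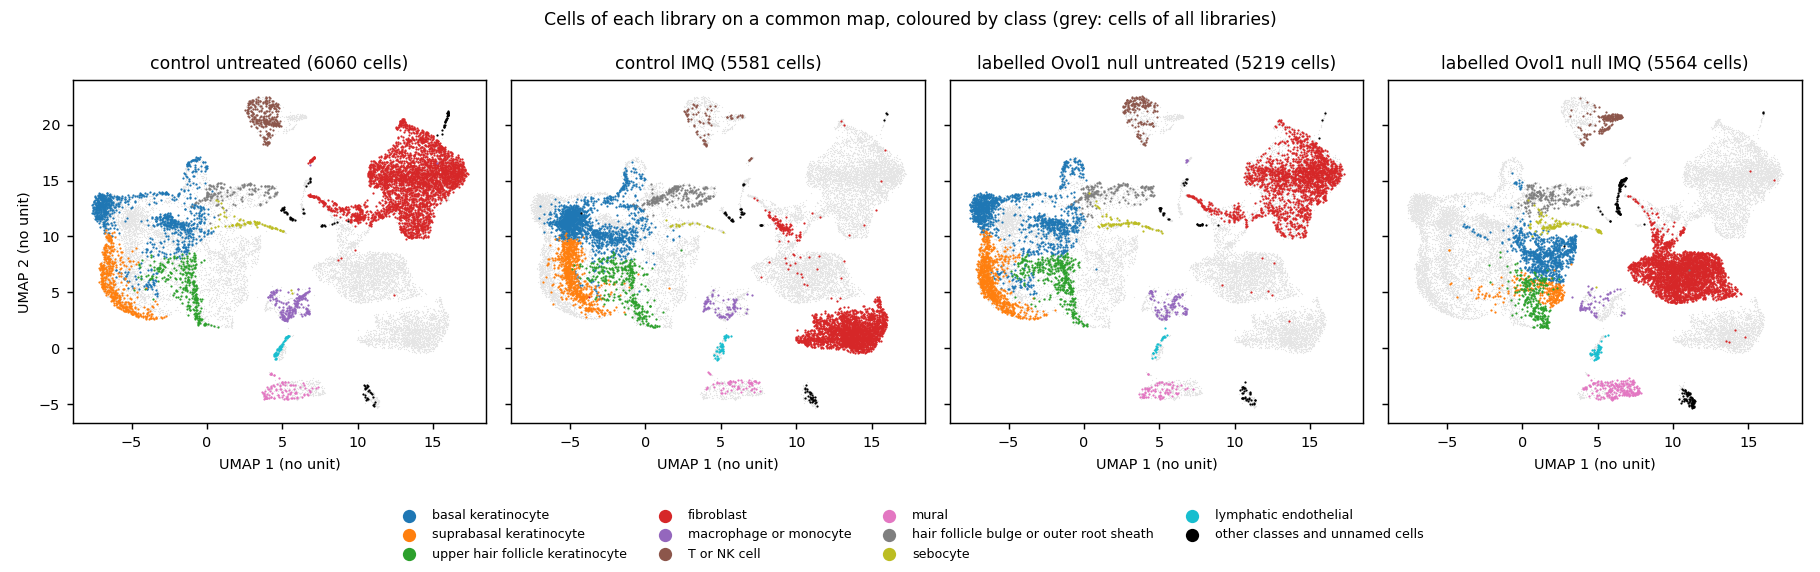
Cells of each library on a common UMAP map (both axes without unit), 1 panel per library, coloured by cell class, with the cells of all libraries in grey. Most fibroblasts of the imiquimod libraries fell in clusters apart from those of the untreated libraries. Keratinocytes of control imiquimod did so in part, since basal clusters 10, 16 and 17 and upper hair follicle cluster 9 also held untreated cells. The panels hold 6060, 5581, 5219 and 5564 cells.

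Ovol1 encodes a zinc-finger transcription factor of epithelia and is the gene the genotype labels name. It lies on chromosome 19 at 5549136 to 5560646 on the minus strand (GRCm38, GENCODE M21, ENSMUSG00000024922), with 4 exons and a 3′ UTR of 1825 bases at 5549136 to 5550960. Ovol1 UMIs were not lower in suprabasal or upper hair follicle keratinocytes of the libraries labelled Ovol1 null. In suprabasal keratinocytes Ovol1 stood at 20.1 CPM (15.5 to 25.7, exact Poisson) in control untreated, 33.6 (29.1 to 38.6) in control imiquimod, 50.2 (44.5 to 56.3) in labelled-null untreated and 199.6 (188.0 to 211.8) in labelled-null imiquimod. The labelled-null libraries were thus 2.5-fold (1.9 to 3.33) above control untreated and 5.94-fold (5.11 to 6.94) above control imiquimod. With 99 cells per library matched for UMIs the ratio over control imiquimod was lower, at 3.844 (2.87 to 5.29). Control imiquimod was 1.67-fold (1.26 to 2.25) above control untreated, a log2 ratio that changed sign to -0.278 with each library clustered on its own. In upper hair follicle keratinocytes Ovol1 stood at 65.3, 53.7, 108.8 and 202.6 CPM. Basal keratinocytes had 30.1, 34.3, 24.2 and 34.9 CPM, and the labelled-null untreated value was 1.25-fold (1.0 to 1.55) below control untreated. The share of basal cells with an Ovol1 UMI was 5.66% (4.30 to 7.28), 8.26% (6.94 to 9.74), 8.71% (7.25 to 10.4) and 29.6% (26.6 to 32.8). Median depth there was 4628.5, 5166, 5269 and 14430 UMIs. After thinning to 1000 UMIs per cell the basal shares were 1.72%, 2.32% (1.63 to 3.20), 1.74% and 4.13% (2.91 to 5.68). An Ovol1 UMI was seen in 11.5% (8.80 to 14.7) of suprabasal cells in control untreated, 19.2% (16.5 to 22.2) in control imiquimod, 22.9% (20.1 to 25.9) in labelled-null untreated and 79.1% (73.8 to 83.8) in labelled-null imiquimod. In fibroblasts, which should lack Ovol1, it was seen in 0.212%, 0.935%, 1.69% and 2.03% of cells. The median depth in labelled-null imiquimod was 19675 UMIs in suprabasal cells and 8028 in fibroblasts. After thinning each cell to 1000 UMIs the suprabasal shares were 2.26%, 2.89%, 4.36% and 17.6% (13.3 to 22.6). The labels do not give which part of the gene was deleted. The reads are 3′ tags, and a tag outside the deleted part checks nothing, so these counts can neither settle the genotype nor show that Ovol1 protein was made. For that reason the libraries are called labelled null in each comparison.

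**Figure D2:**
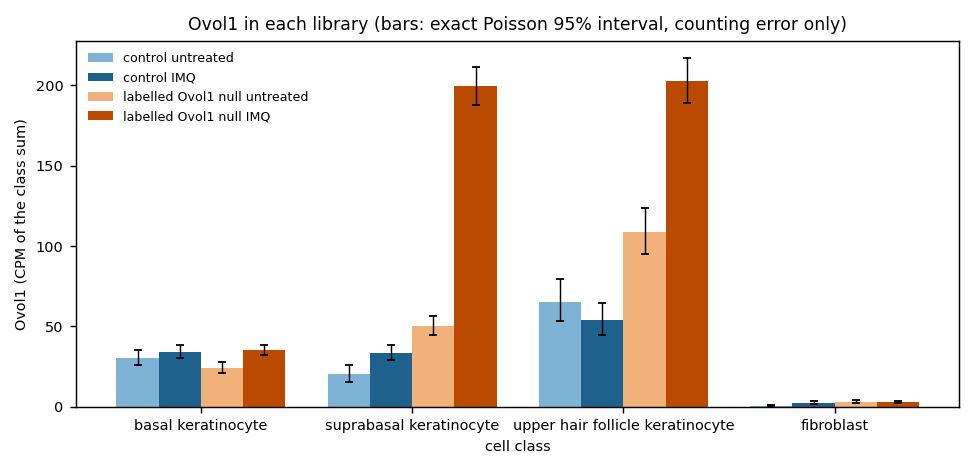
Ovol1 in CPM of the class sum (vertical axis) for 4 cell classes (horizontal axis) in the 4 libraries, with exact Poisson 95% intervals for counting error only. The bars of labelled-null imiquimod reach 199.6 CPM in suprabasal and 202.6 CPM in upper hair follicle keratinocytes, against 33.6 and 53.7 CPM in control imiquimod.

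The first comparison asked what imiquimod did in control skin. Imiquimod engages Toll-like receptors of plasmacytoid dendritic cells and other myeloid cells, and type I interferon is an early product. Interferon switches on antiviral genes in most cell types. Later, cytokines of the IL-17 and IL-1 families push keratinocytes to make activation keratins, alarmins and neutrophil-attracting chemokines. A list member was counted as higher or lower at a ratio of at least 1.5 either way with a counting interval on one side of 1. Medians are of log2 ratios, and a value in square brackets is the median with members at 0 UMIs in one library set to the bound that 3 counts give.

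Most measured interferon-stimulated genes were higher in each class compared. All 17 measured members were higher in basal keratinocytes (median 4.99 [4.64]) and all 14 in suprabasal keratinocytes (median 5.44 [4.63]). Both medians exceeded those of all 10000 random lists of matched expression. In fibroblasts 19 of 19 were higher (median 4.01), in macrophages 12 of 13 (3.49), in T or NK cells 9 of 9 (3.41) and in mural cells 10 of 10 (4.03). Among basal cells Oasl2, which encodes an antiviral 2′-5′-oligoadenylate synthetase-like protein, was 139-fold (59.5 to 429.9) higher. Rtp4, an interferon-induced receptor transporter, was 159.7-fold (54.4 to 776) higher there and Apol9b 381-fold (68.2 to 15078) higher, the last against 1 UMI. Ifi27l2a was 204-fold (130.3 to 338) higher in suprabasal cells and 52.9-fold (45.4 to 62) in fibroblasts, and Irf7, which drives interferon production, 46.5-fold (39.7 to 54.7) in fibroblasts. Oasl2 had 0 UMIs in untreated suprabasal cells and was at least 69.4-fold higher.

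Activation keratins, which mark wounded or inflamed epidermis, were higher mainly in suprabasal cells. There 4 of 4 members were higher (median 4.78 [2.61]), with Krt16 30.1-fold (13.7 to 82.5) and Krt17 6.01-fold (4.92 to 7.42) higher and Krt6a and Krt6b, at 0 UMIs in untreated cells, at least 6.24-fold and at least 4.46-fold. Their levels stayed low, with Krt6a at 5.88 CPM and Krt6b at 4.20 CPM. In basal cells Krt6a was 2.98-fold (2.03 to 4.51) and Krt16 2.59-fold (1.83 to 3.76) higher, and the median of activation keratins was 1.36. With each library clustered on its own both Krt6a and that median stood at -0.225 on the log2 scale. Of alarmins and antimicrobial proteins, 7 of 7 were higher in basal cells (median 2.47) and 4 of 5 in suprabasal cells (median 5.44 [4.61]). S100a8, a subunit of the calcium-binding alarmin calprotectin, was 24.4-fold (14.9 to 42.9) higher in basal cells. Lcn2, which binds bacterial siderophores, was 3.71-fold (2.24 to 6.49) higher there, but its log2 ratio was -1.23 with a stricter cell filter and -1.74 with each library clustered on its own. Krt17 in suprabasal cells went to -0.10 with called doublets kept. The beta-defensin gene Defb6 was 57.7-fold (47.8 to 70.3) higher in suprabasal cells. Of the IL-1 family, 3 of 9 were higher in suprabasal cells, led by the decoy receptor gene Il1r2 at 4.03-fold (3.1 to 5.32), and Il1rn was at 68.8 CPM untreated and 60.1 CPM treated. Il1a and Il1b were near the floor, with 3 and 6 Il1a UMIs and 4.14 and 4.94 Il1b CPM in basal cells of the untreated and treated libraries. Among neutrophil-attracting chemokines in basal cells Cxcl1 was 5.08-fold (3.29 to 8.21) and Cxcl2 2.81-fold (1.22 to 7.53) higher. Other chemokines were higher for 10 of 15 members in basal cells (median 0.88). They included Cxcl10, which attracts CXCR3-bearing T cells, at 14-fold (7.46 to 29.5), and Ccl20, the ligand of CCR6, at 7.92-fold (6.43 to 9.87).

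Most G2 and M phase genes were lower in basal keratinocytes of control imiquimod skin. Of the G2 and M phase list 14 of 16 were lower (median -1.18), among them Top2a 2.56-fold (2.25 to 2.93) and Ube2c 2.54-fold (2.24 to 2.87), and Mki67 stood at 53.3 CPM untreated and 23.1 CPM treated. Of the S phase list 4 of 15 were lower (median -0.37). Of cholesterol synthesis 5 of 10 were lower (median -0.52), led by Idi1 at 3.09-fold (2.25 to 4.26). Hypoxia and glycolysis genes were higher for 11 of 14 members (median 0.87), with the glycolytic enzyme gene Pgk1 4.69-fold (3.73 to 5.95) and Ndrg1 4.08-fold (3.27 to 5.13) higher. The basal cells' largest decreases were in Gpha2, a glycoprotein hormone subunit gene, at 7.92-fold (6.56 to 9.61), the tropomyosin-related Tpm3-rs7 at 6.71-fold (5.03 to 9.05) and Tppp3, a tubulin polymerization-promoting gene, at 6.42-fold (5.79 to 7.14). In suprabasal cells they were Rspo3, a secreted enhancer of Wnt signalling, at 8.16-fold (5.09 to 13.6), Tpm3-rs7 at 7.02-fold (4.86 to 10.4) and Hba-a1 at 6.48-fold (4.86 to 8.74). Of the immediate early and dissociation list 10 of 18 were lower in basal cells (median -0.63), led by Dnajb1 at 1.97-fold (1.83 to 2.12).

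The medians of the barrier lists in suprabasal cells were smaller in size than those of activation keratins and alarmins there. Cornified envelope members were higher for 5 of 9 in suprabasal cells (median 0.78), with the small proline-rich genes Sprr2d 59.2-fold (20.1 to 289) and Sprr1b at least 12.8-fold higher. Flg had 0 and 1 UMIs and Flg2 1 and 1, Lor was at 18.8 and 9.24 CPM (log2 ratio 0.512 with the stricter filter) and Ivl at 3.14 and 3.86 CPM. Of differentiation keratins 1 of 6 was lower (median -0.28), Krt2 at 5.61-fold (3.07 to 10.8). The medians were 0.22 for barrier lipid synthesis, -0.14 for tight and adherens junctions and desmosomes and 0.17 for basement membrane adhesion, with 2 of 14, 3 of 21 and 3 of 12 higher. The claudin gene Cldn1 stood at 74.6 and 94.3 CPM in basal cells. The Nrf2 targets had 1 of 8 lower (median -0.06) and the aryl hydrocarbon receptor targets a median of 0.02 in basal cells. The mesenchymal transition list had a median of -0.41 and the Ovol family and Myc and Id genes one of -0.33, with Ovol2 1.59-fold (1.21 to 2.09) lower. In bulge cells 2 of 3 measured members of the hair growth (anagen) list were lower (median -2.53).

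Control fibroblasts under imiquimod had lower matrix transcripts. Of the fibroblast matrix list 14 of 18 were lower (median -1.47), with the collagen genes Col5a1 7.33-fold (6.75 to 7.98), Col3a1 6.43-fold (6.36 to 6.5) and Col1a1 5.74-fold (5.7 to 5.78) lower. The fibroblast inflammatory list had 4 of 18 higher and 8 of 18 lower (median -0.18). Saa3, an acute-phase serum amyloid gene, was 132-fold (117 to 149) higher and Has1, a hyaluronan synthase gene, 5.81-fold (4.95 to 6.86) lower. Other large decreases were in Pycr1, an enzyme gene of proline synthesis, at 57.1-fold (30.9 to 119), Crabp1, which binds retinoic acid, at 32.2-fold (24.6 to 42.9), and Tppp3 at 16.3-fold (14.8 to 18.1). Neutrophil-attracting chemokines were lower for 3 of 3 members (median -1.83), Il6 at 3.56-fold (3.12 to 4.07) and Cxcl1 at 1.64-fold (1.38 to 1.97). Lcn2 was 62.6-fold (37.6 to 113) higher.

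Macrophages of control imiquimod skin showed the B-cell-attracting chemokine gene Cxcl13 at least 204-fold higher, the endothelial lipase gene Lipg at least 128-fold and Saa3 736-fold (131 to 29199), the last against 1 UMI. Igfbp5 was 22.3-fold (13 to 42) lower, the collagen chaperone gene Serpinh1 16.5-fold (11.1 to 25.9) and Col1a1 10.2-fold (9.28 to 11.2). Fibroblasts had more of these 3 and of Saa3, with Col1a1 at 38534 CPM against 10057 CPM in macrophages of control untreated and Saa3 at 1586 CPM against 467 CPM in control imiquimod, so these ratios were not separated from fibroblast RNA in these cells. The inflammatory monocyte and macrophage list had 5 of 13 higher (median 0.15) and the resident macrophage list 6 of 13 (median 0.51), led by the complement gene C1qb at 6.23-fold (5.29 to 7.36). In the MHC class II list H2-Eb1 alone was lower, at 8.04-fold (7.01 to 9.26). Among type 17 lymphocyte genes in T or NK cells, Il17a was 2.36-fold (2.15 to 2.59) and Il17f 2.36-fold (2.03 to 2.73) higher and Il22 6.51-fold (3.25 to 15.3) lower. Lymphatic and blood endothelial cells numbered under 50 in at least 1 library of each comparison, so the endothelial adhesion list was not compared. TMM scaling moved the median log2 ratio of all genes by 0.20 in basal, 0.14 in suprabasal and 0.16 in upper hair follicle keratinocytes and by -0.18 in T or NK cells. The share of called listed genes that were higher then went from 55.2% to 66.4%, from 73.3% to 84.6% and from 80.9% to 66.0% in basal, upper hair follicle and T or NK cells.

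**Figure D3:**
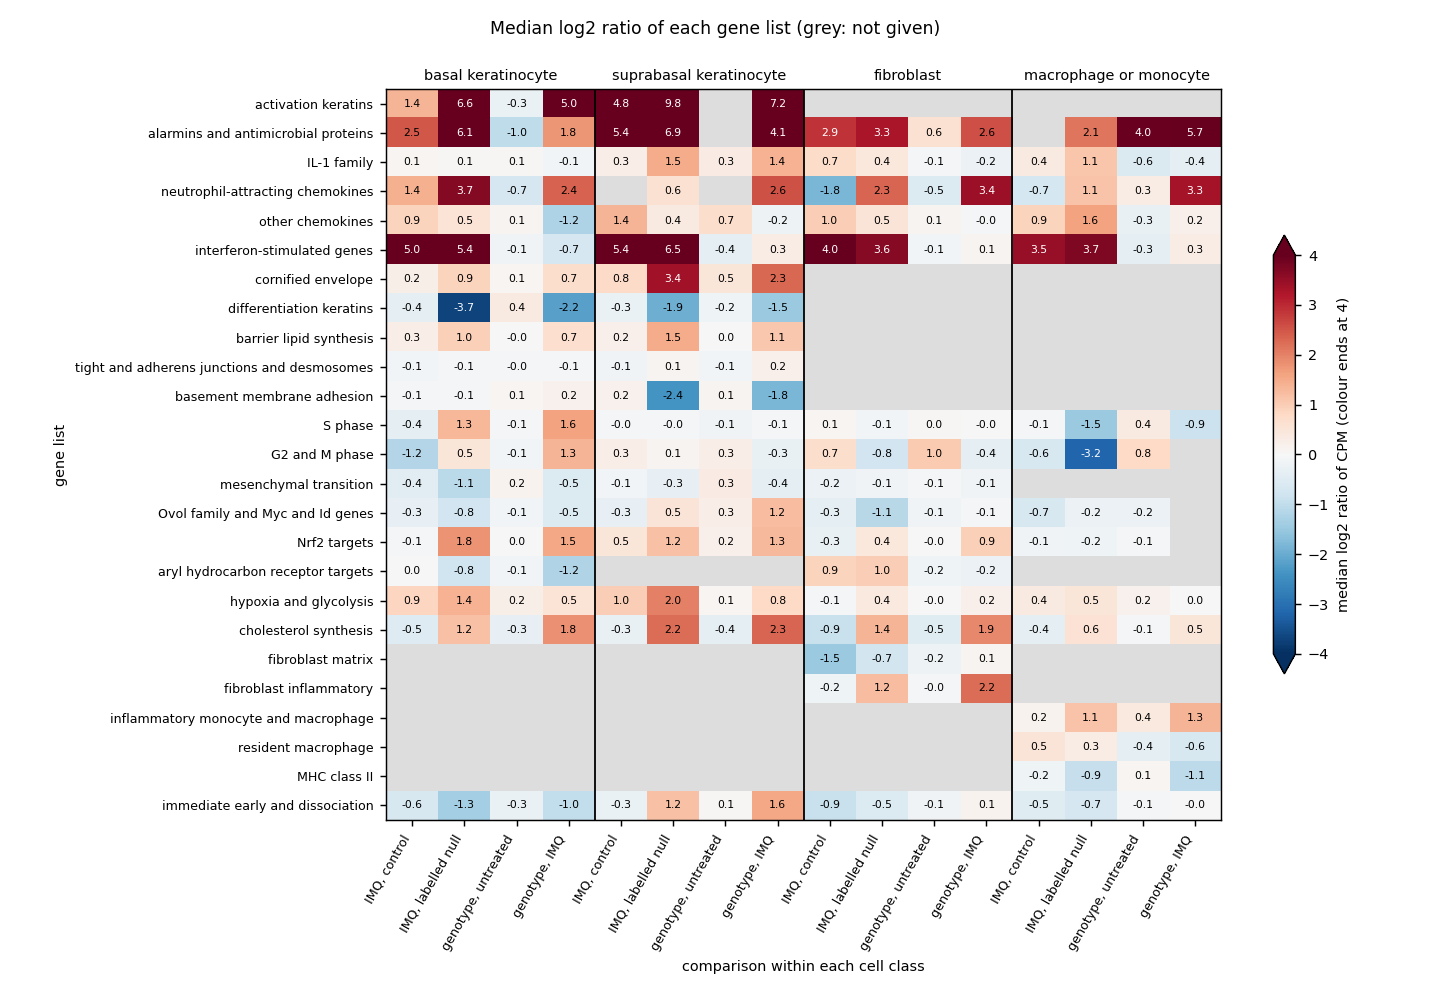
Median log2 ratio of CPM (colour, ends at 4) for each gene list (vertical axis) and comparison within each of 4 cell classes (horizontal axis); grey marks lists not given. Interferon-stimulated genes are high in both imiquimod comparisons in each class, at 4.99 and 5.45 in basal keratinocytes, and near 0 without treatment.

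The next comparison asked what imiquimod did in the libraries labelled Ovol1 null. OVOL1 is described as a brake on proliferation that helps keratinocytes leave the cell cycle and differentiate. Alarmins, activation keratins and cycling genes are programmes often read in stressed epidermis. Because Ovol1 UMIs were not lower in suprabasal cells of these libraries, a direction found here belongs to the labels and not to a measured loss of the gene.

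Interferon-stimulated genes were again higher, for 18 of 18 members in basal (median 5.45 [4.67]) and 15 of 15 in suprabasal keratinocytes (median 6.53 [5.31]), 19 of 20 in fibroblasts (3.63 [3.52]), 12 of 13 in macrophages (3.75), 8 of 8 in T or NK cells (3.30) and 16 of 16 in mural cells (4.70 [3.37]). Ifi27l2a was 65.5-fold (55.9 to 77.4) higher in basal and 224-fold (151 to 346) in suprabasal cells.

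Alarmins and activation keratins had the greatest medians of the lists in basal and suprabasal keratinocytes. Of alarmins and antimicrobial proteins 8 of 8 were higher in basal (median 6.13 [5.39]) and 8 of 8 in suprabasal cells (median 6.93). S100a8 was 9028-fold (4582 to 20911) and its partner S100a9 6092-fold (2799 to 16602) higher in basal cells. In suprabasal cells S100a8 was 28326-fold (9692 to 137359) higher, against 3 UMIs, and S100a9 6553-fold (3180.4 to 16301). Lcn2 was 129.7-fold (65.7 to 301) higher in basal cells and the beta-defensin gene Defb3 at least 43.6-fold. All 4 activation keratins were higher in both classes (medians 6.63 and 9.78), with Krt6b at least 3526-fold, Krt6a 1614-fold (741 to 4399), Krt16 525-fold (398 to 708) and Krt17 16.1-fold (15 to 17.4) higher in suprabasal cells. With joint clusters alone, Krt17 there stood at -0.26 on the log2 scale and the IL-1 family median at -0.0635. Sprr2h was at least 205-fold higher in basal cells. The IL-1 family had 7 of 11 higher in suprabasal cells (median 1.49), led by Il1f8 at 98.2-fold (17.2 to 3919) against 1 UMI and Il1f9 at 11.5-fold (8.33 to 16.4). Il1rn stood at 58.1 and 164 CPM and Il1a at 0 and 10 UMIs. Neutrophil-attracting chemokines were higher for 4 of 4 members in basal cells (median 3.66), Cxcl1 at 34.5-fold (22.2 to 56.6), Cxcl2 at 4.83-fold (3.44 to 6.95) and Cxcl3, against 1 UMI, at 60.04-fold (10.5 to 2393). Other chemokines went both ways, with 8 of 16 higher and 5 of 16 lower in basal cells. Ccl27a, which attracts skin-homing T cells, was 22.5-fold (21.7 to 23.4) lower and Ccl20 8.51-fold (7.19 to 10.2) higher.

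Genes of DNA replication and of sterol synthesis were higher in basal cells. Of the S phase list 14 of 16 were higher (median 1.31), with Ccne1 22.4-fold (8.6 to 83.4) and Mcm5 4.22-fold (3.48 to 5.16) higher, and of the G2 and M phase list 6 of 16 (median 0.49), with Cenpa 2.08-fold (1.87 to 2.32) higher. Mki67 stood at 36.5 and 41.7 CPM. Cholesterol synthesis had 8 of 10 higher in basal (median 1.17) and 10 of 10 in suprabasal cells (median 2.22), Sqle, the squalene epoxidase gene, at 10.6-fold (7.03 to 16.7) and 8.71-fold (7.03 to 10.9). Nrf2 targets had 7 of 9 higher in basal cells (median 1.81), Slc7a11, a cystine transporter gene, at 74.6-fold (20.5 to 619). Hypoxia and glycolysis had 12 of 14 higher in suprabasal cells (median 2.01), with adrenomedullin, Adm, at 23.8-fold (14 to 44). Aryl hydrocarbon receptor targets had 2 of 4 lower in basal cells, Tiparp at 2.25-fold (2.0 to 2.54).

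Most cornified envelope genes were higher and several differentiation keratins lower. In suprabasal cells 8 of 10 cornified envelope members were higher (median 3.36), with Sprr1b at least 832-fold and Sprr2d at least 480.3-fold. Ivl stood at 6.66 and 20.8 CPM, Lor at 9.82 and 4.35 CPM, and Flg at 0 and 12 UMIs. Barrier lipid synthesis had 13 of 16 higher (median 1.47), Sdr9c7 at 77.5-fold (13.5 to 3103) against 1 UMI. Of the differentiation keratins 6 of 6 were lower in basal (median -3.70) and 4 of 6 in suprabasal cells (median -1.95), Krt77 at 39-fold (28.2 to 55.5) and 5.82-fold (5.49 to 6.18). Basement membrane adhesion had 9 of 11 lower in suprabasal cells (median -2.39), Krt15 at 35.6-fold (33 to 38.5) and Col17a1 at 9.91-fold (8.65 to 11.4). Krt15 and Col17a1 are also basal markers that named the classes. Their ratios were not separated from where the line between basal and suprabasal cells fell. Tight and adherens junctions and desmosomes had 7 of 21 higher there, the claudin gene Cldn4 at 12.1-fold (8.46 to 17.8), while Cldn1 was 1.61-fold (1.41 to 1.84) lower in basal cells (log2 ratio 0.898 with joint clusters alone). Further decreases were in Gpha2 at 34.6-fold (22.7 to 55.1) and Bbox1, of carnitine synthesis, at 28.5-fold (19.9 to 42.1) in basal cells, and in Hba-a1 at 186-fold (117 to 314) and Igfbp3 at 29.5-fold (19.7 to 46.4) in suprabasal cells. The mesenchymal transition list had 5 of 6 lower in basal cells, Fn1 at 5.79-fold (3.86 to 8.9). The Ovol family and Myc and Id genes had 4 of 6 lower there, and in suprabasal cells Ovol1 was 3.98-fold (3.49 to 4.55) higher and Ovol2 2.59-fold (1.89 to 3.59) lower. Genes of the immediate early and dissociation list were lower for 14 of 18 members in basal and higher for 14 of 18 in suprabasal cells (medians -1.35 and 1.17), the latter at -0.611 with called doublets kept. Haemoglobin transcripts varied between libraries, Hba-a1 standing at 67.5, 10.4, 605.6 and 3.26 CPM in suprabasal cells of control untreated, control imiquimod, labelled-null untreated and labelled-null imiquimod. An Hba-a1 UMI was seen in 14.8% of suprabasal cells of labelled-null untreated and 6.23% of labelled-null imiquimod, a far smaller difference than the 186-fold ratio.

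Fibroblasts of the labelled-null pair had more inflammatory transcripts under imiquimod. The fibroblast inflammatory list had 12 of 18 higher and 0 of 18 lower (median 1.25), with Saa3 204-fold (192 to 216), Timp1, a metalloproteinase inhibitor gene, 19.5-fold (17.8 to 21.4), and the alarmin cytokine gene Il33 13.9-fold (10.3 to 19.4) higher. Lcn2 was 558-fold (353 to 941) and Saa1 479-fold (252 to 1049) higher. Neutrophil-attracting chemokines had 4 of 4 higher (median 2.33), Cxcl2 at 5.7-fold (4.14 to 8.04) and Cxcl1 at 4.47-fold (3.97 to 5.06), and cholesterol synthesis 8 of 10 (median 1.35). The fibroblast matrix list had 11 of 18 lower (median -0.74), Col5a1 at 4.68-fold (4.42 to 4.96), while Tnc, the tenascin C gene of wounded matrix, was 26-fold (19.5 to 35.5) higher. Other large decreases were in Gng13, a G-protein gamma subunit gene, at 64.1-fold (41.5 to 104), the potassium channel subunit gene Kcng2 at 44.9-fold (25.3 to 88.1) and Mamdc2 at 28.2-fold (19.8 to 41.5).

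Macrophages of the labelled-null pair had Cxcl13 at least 454-fold, Saa3 1242-fold (485 to 4563) and Lipg at least 82.3-fold higher under imiquimod. The keratinocyte transcripts Krt77, Krt15 and Ccl27a were 140.3-fold (24.9 to 5568), 72-fold (32.9 to 197) and 66.8-fold (28.4 to 207) lower, the Krt77 value against 1 UMI. Saa3 was higher still in fibroblasts of that library and the last 3 in keratinocytes of labelled-null untreated, so these ratios were not separated from RNA of those cells. The inflammatory monocyte and macrophage list had 10 of 14 higher (median 1.15), with Clec4e 6.55-fold (4.31 to 10.3) and Trem1 10.5-fold (3.65 to 41.2). Clustered on its own, labelled-null imiquimod had no macrophage or monocyte cluster, but 144 Langerhans-like cells and 13 neutrophils. The classes used here held 92 and 1 of these, so its 63 macrophages may include both. Ratios of this class were not separated from such a difference in make-up. The resident macrophage list had 6 of 13 higher and 6 of 13 lower. Of MHC class II 5 of 7 were lower (median -0.91), Cd74 at 2.17-fold (2.11 to 2.23). In T or NK cells Il17f was 3.59-fold (3.18 to 4.06), Il17a 3.27-fold (3.05 to 3.51) and Il22 2.54-fold (1.63 to 4.12) higher, and of the type 17 lymphocyte genes 3 of 10 were higher and 3 of 10 lower. Of the hair growth (anagen) list 2 of 4 were lower in bulge cells.

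Most keratinocytes of labelled-null imiquimod were named in a clustering of that library alone. With the joint clusters alone, 122 basal and 63 suprabasal cells of that library remained. Of these basal cells 82 were in cluster 10, which had upper hair follicle markers among its top genes. The basal medians were then 3.02 for activation keratins, 6.41 for alarmins and antimicrobial proteins, 5.66 for interferon-stimulated genes and 1.17 for S phase. The cornified envelope and barrier lipid synthesis medians changed sign to -1.46 and -0.83. Cluster 3 had been left unnamed because S100a8 and S100a9 are neutrophil markers. This alternative thus leaves out cells by their alarmins, and it does not check the alarmin medians in like cells. TMM scaling moved the median of all genes by 0.24 in basal, 0.19 in suprabasal and 0.21 in upper hair follicle keratinocytes, by 0.23 in fibroblasts and 0.16 in mural cells, and by -0.12 in macrophages and -0.13 in sebocytes.

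**Figure D4:**
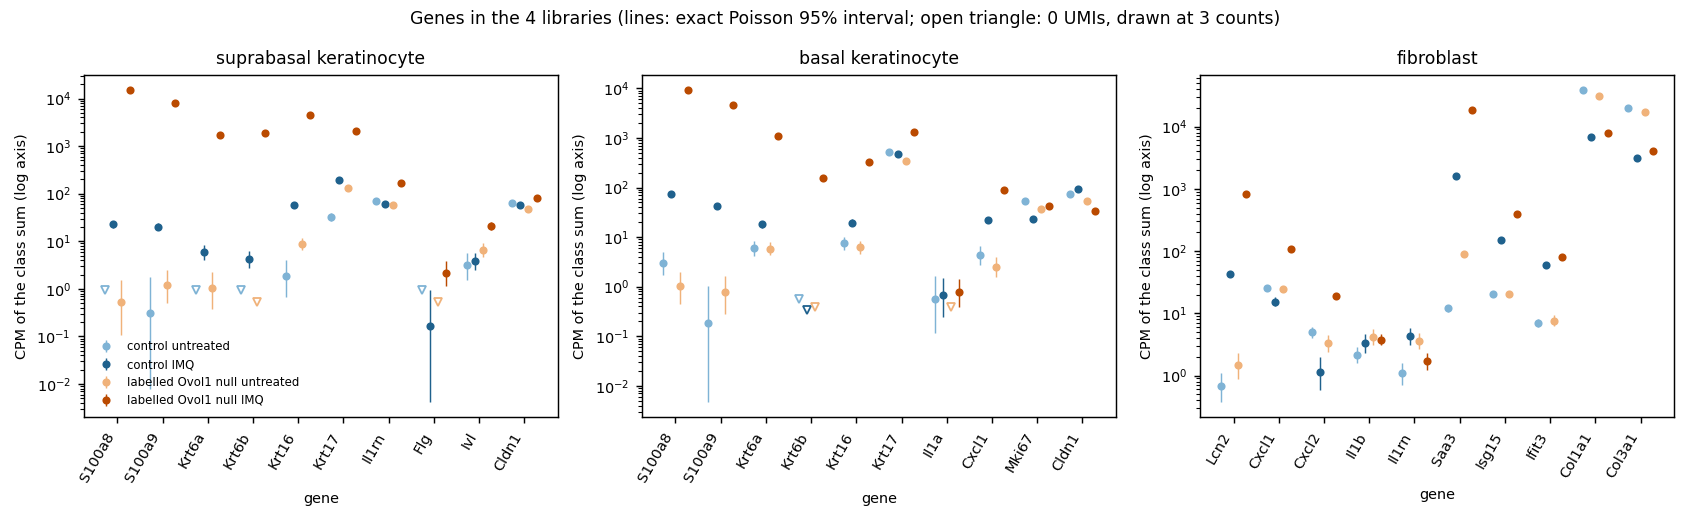
CPM of the class sum (log axis) for chosen genes (horizontal axis) in the 4 libraries, 1 panel each for suprabasal keratinocytes, basal keratinocytes and fibroblasts. Lines are exact Poisson 95% intervals and open triangles mark 0 UMIs drawn at 3 counts; S100a8 in suprabasal cells stands at 23.0 CPM in control imiquimod and 14904 CPM in labelled-null imiquimod.

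The third comparison asked how untreated skin labelled Ovol1 null differed from untreated control skin. Without treatment both libraries had similar depth, with medians of 5704.5 and 5706 UMIs per cell. The labels speak of a null allele, but Ovol1 UMIs were higher in suprabasal cells of the labelled-null library, so the direction of each ratio is tied to the labels only.

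In keratinocytes the number of listed genes that differed depended on the classes. Of the 234 listed genes measured in basal cells 14 were higher and 12 lower in the labelled-null library, and of 197 in suprabasal cells 30 were higher and 5 lower. With each library clustered on its own 56 were lower in basal and 47 higher in suprabasal cells, and with called doublets kept 26 were higher in basal and 21 lower in suprabasal cells. In suprabasal cells Krt17 was 4.02-fold (3.27 to 4.99) and Krt16 4.65-fold (1.99 to 13.3) higher, and Defb6 2.15-fold (1.74 to 2.68). With called doublets kept the log2 ratios of Krt17 and Krt16 were -0.831 and -0.333. In basal cells Krt17 was 1.48-fold (1.41 to 1.56) lower, and S100a8 2.96-fold (1.2 to 8.0) and Lcn2 3.33-fold (1.38 to 8.86) lower at few UMIs. The medians of activation keratins and alarmins and antimicrobial proteins there were -0.28 and -1.03. The interferon-stimulated genes had a median of -0.13 in basal cells, G2 and M phase one of -0.12, S phase one of -0.06, and basement membrane adhesion one of 0.07, with 0 members of the last 3 lists higher or lower. In basal cells Mki67 was 1.46-fold (1.24 to 1.73) lower and Cldn1 1.38-fold (1.2 to 1.58). In suprabasal cells the cornified envelope had 3 of 8 higher and 1 of 8 lower, the latter Lor at 1.92-fold (1.31 to 2.81). Neither differentiation keratins nor barrier lipid synthesis had a member higher or lower in suprabasal cells.

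Several of the largest ratios recurred in unrelated classes. Baiap2l1, a membrane-bending actin regulator gene, was 11.1-fold (9.11 to 13.7) higher in basal and 13.5-fold (10.3 to 18.2) in suprabasal cells. Tpm3-rs7 was 5.08-fold (3.88 to 6.73) lower in basal cells, 5.66-fold (4.0 to 8.13) in suprabasal cells and 10.6-fold (7.97 to 14.5) in fibroblasts. The ribosomal protein pseudogene Rps26-ps1 was 4.23-fold (3.91 to 4.58) higher in suprabasal cells, 5.11-fold (4.81 to 5.42) in fibroblasts and 5.11-fold (4.08 to 6.44) in macrophages. In basal cells the histone gene Hist1h2ap was 6.35-fold (5.34 to 7.59) and BC100530 6.16-fold (4.78 to 8.05) higher, and Agpat4, an acyltransferase gene, 3.92-fold (2.96 to 5.23) and the heme-binding gene Hebp2 3.76-fold (3.0 to 4.74) lower. In suprabasal cells Hba-a1 was 8.97-fold (7.81 to 10.3) higher, and Hebp2 3.03-fold (2.58 to 3.57) and the cholesterol transporter gene Npc1 2.73-fold (2.23 to 3.36) lower. Fewer suprabasal cells had an Hba-a1 UMI in labelled-null untreated, 14.8% against 21.8% in control untreated. Its ratio thus came from more UMIs in the cells that had any. In fibroblasts AY036118 was 5.69-fold (4.93 to 6.58) and Pla2g2e, a secreted phospholipase gene, 4.77-fold (4.25 to 5.36) higher, and Tmem107 2.24-fold (1.97 to 2.56) and Ergic1 2.13-fold (1.88 to 2.42) lower.

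Fibroblasts had 59 of 246 listed genes higher and 15 lower. The listed genes include those of the epithelial lists. Epithelial classes held 33.0% of cells in control untreated and 53.7% in labelled-null untreated. Ovol1 stood at 0.317 and 2.79 CPM in fibroblasts of these libraries, so keratinocyte RNA was not excluded for these counts. The fibroblast matrix list had 0 higher and 0 lower (median -0.21). Saa3 was 7.48-fold (6.53 to 8.58) higher, and cholesterol synthesis had 4 of 10 lower (median -0.50). In macrophages H2-Eb1, a class II antigen-presentation gene, was 30.5-fold (24.8 to 37.8) lower while the other MHC class II genes were neither higher nor lower. Ms4a4d was 14.4-fold (3.81 to 122) lower, against 2 UMIs, and the chemokine gene Ccl8 4.3-fold (3.76 to 4.93). Hist1h2ap was 10.9-fold (7.36 to 16.7) and Krt77, a transcript of suprabasal cells, 6.87-fold (5.19 to 9.21) higher there. In T or NK cells the type 17 lymphocyte genes had 3 of 10 higher, with Cd163l1 3.26-fold (2.62 to 4.08), and Il22 was 4.49-fold (2.96 to 7.09) lower. In upper hair follicle keratinocytes 43.75% of the called listed genes were higher, and 56.7% after TMM scaling.

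The last comparison between libraries asked how imiquimod-treated skin labelled Ovol1 null differed from imiquimod-treated control skin. Both libraries carried an interferon response, so differences in the other programmes could be read against it. In addition to genotype and mice, these libraries differed in depth, at 4760 and 8395.5 median UMIs per cell, and in the lowest UMI count of a cell. They also differed in the make-up of the basal class. Cluster 10, with upper hair follicle markers among its top genes, gave 384 of 1550 basal cells in control and 82 of 871 in labelled-null imiquimod. Ovol1 CPM was higher in suprabasal and upper hair follicle keratinocytes of the labelled-null library here too, but not in basal cells. The share of basal cells with an Ovol1 UMI was higher there, at 29.6% against 8.26%, or 4.13% against 2.32% after thinning to 1000 UMIs.

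Alarmins and activation keratins stood far above control in keratinocytes of the labelled-null library. In basal cells S100a8 was 125-fold (116 to 135), S100a9 109-fold (98.9 to 121) and Krt6a 60.8-fold (52 to 71.5) higher. In suprabasal cells S100a8 was 648-fold (548 to 771), S100a9 396-fold (331 to 477), Defb3 at least 417-fold, Krt6b 442-fold (299 to 683), Krt6a 289-fold (208 to 415) and Krt16 81.4-fold (73.1 to 90.9) higher. S100a8 stood at 14904 CPM there against 23.0 CPM. The medians of alarmins and antimicrobial proteins were 1.78 in basal and 4.11 in suprabasal cells, with 7 of 9 and 7 of 9 higher, and those of activation keratins 5.01 and 7.25. The interferon-stimulated genes did not share this shift. In basal cells 1 of 18 were higher and 11 of 18 lower (median -0.67), Ifit1 at 3.68-fold (3.2 to 4.26), and in suprabasal cells 5 of 18 were higher and 0 of 18 lower (median 0.31). Neutrophil-attracting chemokines had 4 of 4 higher in basal cells (median 2.37), with Cxcl2 6.29-fold (4.39 to 9.3) and Cxcl1 3.98-fold (3.42 to 4.65). Of other chemokines 10 of 16 were lower, led by Ccl27a at 28.7-fold (27.6 to 29.8), and the median was -1.23, or 0.373 with called doublets kept. Its neighbour Ccl27b was 31.1-fold (22 to 45.3) lower. The IL-1 family had 6 of 11 higher in suprabasal cells, Il1f8 at 20.5-fold (8.48 to 64.6) and Il1f6 at 20.1-fold (8.3 to 63.3).

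Cycling genes were higher in basal cells of the labelled-null library, 16 of 16 of the S phase list (median 1.62) and 14 of 16 of the G2 and M phase list (median 1.35). Rrm2, a subunit gene of ribonucleotide reductase, was 4.56-fold (3.78 to 5.54) and Plk1, a mitotic kinase gene, 4.28-fold (2.93 to 6.46) higher. Mki67 stood at 23.1 CPM in control and 41.7 CPM in labelled-null imiquimod (log2 ratio -0.00138 with each library clustered on its own). Cholesterol synthesis had 9 of 10 higher in basal (median 1.82) and 10 of 10 in suprabasal cells (median 2.32), Sqle at 14.4-fold (9.2 to 23.8) and Idi1 at 7.26-fold (6.05 to 8.77). Nrf2 targets had 8 of 9 higher (median 1.54) and hypoxia and glycolysis 7 of 14 (median 0.54) in basal cells. Cornified envelope members were higher for 8 of 10 in suprabasal cells (median 2.29), Sprr1b at 36.2-fold (28.6 to 46.4), and barrier lipid synthesis for 12 of 16 (median 1.07). Basement membrane adhesion had 10 of 12 lower in suprabasal cells (median -1.84), Krt15 at 39.3-fold (36.4 to 42.4). Several of its members are basal markers that named the classes, so where the class line fell was not separated from this. The differentiation keratins had 4 of 5 lower in basal cells, Krt77 at 27.8-fold (20.02 to 39.6), and their median was -2.17, or 0.715 with each library clustered on its own. Cldn1 was 2.81-fold (2.51 to 3.15) lower in basal cells (log2 ratio 0.0983 with joint clusters alone). In suprabasal cells Serpina3j was 191-fold (52.5 to 1582) lower, against 2 UMIs. The Ovol family and Myc and Id genes had 4 of 6 higher there, Id1 at 5.24-fold (4.33 to 6.37), and immediate early and dissociation genes 16 of 18 (median 1.56, or -0.408 with called doublets kept), Atf3 at 7.87-fold (6.97 to 8.92).

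In fibroblasts the fibroblast inflammatory list had 15 of 18 higher (median 2.23), Saa3 at 11.6-fold (11.4 to 11.7) and Timp1 at 10.002-fold (9.32 to 10.7). Tnc was 81-fold (47.3 to 152) higher, the osteoprotegerin gene Tnfrsf11b 41.2-fold (22.3 to 86.3) and Saa1 23.3-fold (19.96 to 27.5). Arl4d, a small GTPase gene, was 22.1-fold (18.7 to 26.3), Gpr1 22.1-fold (18.6 to 26.5) and Trp53inp1, a p53-induced gene, 12.5-fold (10.8 to 14.4) lower. Neutrophil-attracting chemokines had 4 of 4 higher (median 3.42 [2.34]) and cholesterol synthesis 9 of 10 (median 1.92). The fibroblast matrix list had a median of 0.10. In macrophages S100a9 was 1138-fold (204 to 44972) and S100a8 1049-fold (188 to 41472) higher, each against 1 UMI, and the lipolysis inhibitor gene G0s2 at least 60.6-fold. Cd209e, against 2 UMIs, was 90.2-fold (24.6 to 751), Krt15 63.1-fold (28.7 to 173) and the lectin gene Cd209a 26-fold (13.9 to 54.9) lower. The ratios of S100a8, S100a9 and Krt15 were not separated from keratinocyte RNA in these cells, and suprabasal cells of labelled-null imiquimod had 14904 CPM of S100a8 against 2247 CPM in macrophages. G0s2 and S100a9 were among the top genes of 13 cells named neutrophils when labelled-null imiquimod was clustered on its own. The classes used here named 1 neutrophil there, so neutrophils among these macrophages were not excluded as a source. The inflammatory monocyte and macrophage list had 9 of 13 higher, the resident macrophage list 7 of 12 lower and MHC class II 4 of 6 lower. These counts were not separated from Langerhans-like cells and neutrophils among the macrophages of labelled-null imiquimod. In T or NK cells the type 17 lymphocyte genes had 6 of 9 higher (median 0.86), Il17a at 2.03-fold (1.88 to 2.2).

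With joint clusters alone the labelled-null over control medians in basal cells were 1.79 for activation keratins, 1.54 for alarmins and antimicrobial proteins and 1.77 for S phase, -1.25 for the cornified envelope and -0.425 for barrier lipid synthesis, and Krt17 in suprabasal cells stood at -0.73. TMM scaling moved the median of all genes by 0.24 in fibroblasts, 0.14 in T or NK cells and 0.22 in mural cells, and in fibroblasts the share of called listed genes that were higher went from 49.4% to 59.7%.

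The last question was whether imiquimod acted differently in the labelled-null and control pairs of libraries. The effect of treatment in one pair was set against that in the other, gene by gene. No library entered both effects. A difference between them was read from counts alone, with 95% intervals from gamma draws of the 4 counts used in the rule for higher and lower, and was not tested against variation between mice.

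Across 11047 genes in basal keratinocytes the log2 ratios of both pairs had a Pearson correlation of 0.383 and a Spearman correlation of 0.173. In suprabasal keratinocytes these were 0.486 and 0.311 over 9720 genes, in fibroblasts 0.385 and 0.261 over 12274 genes, and in macrophages 0.401 and 0.280 over 5488 genes. These are correlations across genes, and genes are not independent replicates. Without interferon-stimulated genes the Pearson values were 0.347, 0.461, 0.367 and 0.383. The median difference, labelled-null minus control on the log2 scale, was 4.37 (3 of 3 members higher, 0 lower) for activation keratins in basal and 4.76 (3 of 4 members higher, 0 lower) in suprabasal keratinocytes. For alarmins and antimicrobial proteins it was 1.79 (4 of 7 members higher, 0 lower) and 4.10 (3 of 5 members higher, 0 lower). For cholesterol synthesis it was 1.71 (9 of 10 members higher, 0 lower) in basal cells and 2.27 (8 of 10 members higher, 0 lower) in fibroblasts. The G2 and M phase list gave 1.44 (15 of 16 members higher, 0 lower) in basal cells, -1.41 (0 of 8 members higher, 4 lower) in fibroblasts and -2.53 (0 of 10 members higher, 7 lower) in macrophages. S phase gave 1.67 (14 of 15 members higher, 0 lower) in basal and 0.01 (0 of 11 members higher, 1 lower) in suprabasal cells and -1.52 (0 of 7 members higher, 4 lower) in macrophages, and Nrf2 targets 1.48 (6 of 8 members higher, 0 lower) in basal cells. Interferon-stimulated genes gave -0.19 (2 of 17 members higher, 2 lower) in basal and 0.47 (1 of 14 members higher, 0 lower) in suprabasal cells, 0.01 (4 of 19 members higher, 3 lower) in fibroblasts and 0.74 (2 of 12 members higher, 0 lower) in macrophages. The fibroblast inflammatory list gave 2.24 (15 of 18 members higher, 2 lower). Differentiation keratins in basal cells gave -3.07 (0 of 5 members higher, 4 lower) and basement membrane adhesion in suprabasal cells -2.28 (2 of 11 members higher, 9 lower). Members of both lists are also markers that named the classes, so where the class line fell was not separated from these differences.

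**Figure D5:**
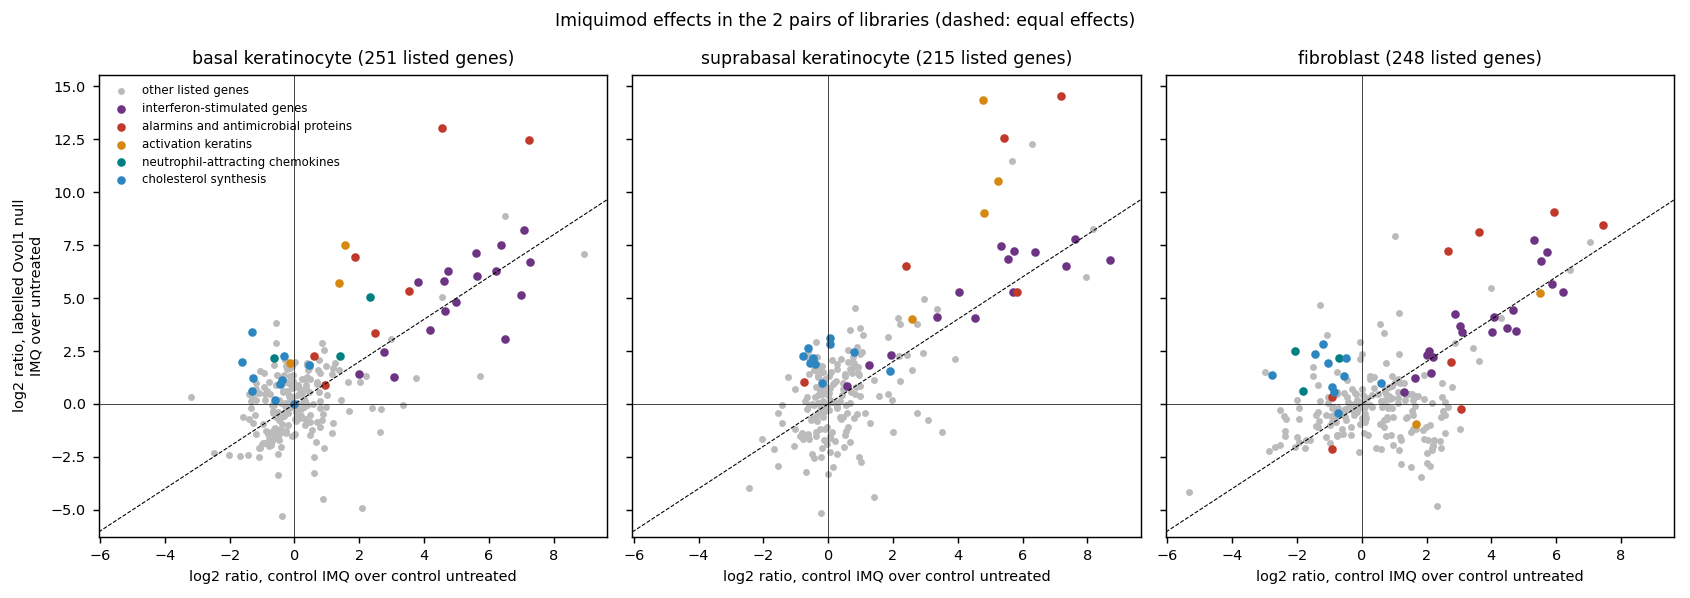
Log2 ratio of control imiquimod over control untreated (horizontal axis) against that of labelled-null imiquimod over labelled-null untreated (vertical axis) for listed genes in basal and suprabasal keratinocytes and fibroblasts; the dashed line marks equal effects. Interferon-stimulated genes lie on both sides of the line, with a median difference of -0.19 in basal keratinocytes, and activation keratins lie above it, with one of 4.37.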

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

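All tests of explanations given here were chosen only after the result was seen, so each can exclude an explanation but not establish one. With 1 library per group, mouse, preparation and group cannot be separated.

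Imiquimod effects of opposite sign were seen in the control pair and in the pair labelled Ovol1 null at a median of at least 1.5-fold each way for 3 lists in fibroblasts and 1 in macrophages, and the difference was not tested. Further lists, such as S phase and cholesterol synthesis in basal keratinocytes, had medians of opposite sign with at least 1 of them nearer to 0. The median log2 ratio of neutrophil-attracting chemokines in fibroblasts was -1.83 in the control pair and 2.33 in the labelled-null pair. That of cholesterol synthesis in fibroblasts was -0.89 and 1.35, and that of G2 and M phase genes in fibroblasts 0.69 and -0.76. Keratinocyte transcripts in the fibroblast class, chosen after their values were seen, moved the same way as the last, with log2 ratios of 2.43 and -1.75 for Krt1, 2.15 and -2.06 for Dsp, 2.43 and -2.08 for Perp and 3.02 and -1.20 for Krtdap. Epithelial classes held 33.0% and 51.8% of cells in the control pair and 53.7% and 30.9% in the labelled-null pair, so keratinocyte RNA in the fibroblast class was not excluded for the G2 and M phase list. In macrophages or monocytes, with 83 and 63 treated cells, neutrophil-attracting chemokines had medians of -0.69 and 1.14. With labelled-null imiquimod clustered on its own, Cxcl2 was among the top genes of 13 cells named neutrophils. Neutrophils in the macrophage class were therefore not excluded. What set the pairs apart was the sign of a median over single libraries, and no biological explanation was tested for these 4 lists.

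Ovol1 UMIs were higher, not lower, in suprabasal keratinocytes of the libraries labelled Ovol1 null. Free RNA as the whole source is argued against: fibroblasts of the labelled-null imiquimod library had 1.275% of the Ovol1 CPM of its suprabasal cells, where free RNA would have given like levels. Depth and the UMI minimum as the whole source are argued against as well. With 99 suprabasal cells per library matched for UMIs (medians of 11975 and 11729) the labelled-null over control ratio under imiquimod was 3.844 (2.87 to 5.29). That was lower than over all cells. Exchanged genotype labels cannot be told apart from a true null whose transcript persists, because Ovol1 was higher in the labelled-null library in 4 of 6 comparisons of keratinocyte classes and the deleted part of the gene is not given in the sources used here. A null allele that leaves the 3′ end transcribed may therefore remain a candidate explanation, untested.

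Alarmins were far higher in keratinocytes of the labelled-null imiquimod library than in those of control imiquimod. Neutrophil RNA in the basal cells is argued against: the other 7 neutrophil markers held 571 UMIs, which is 3.732% of the 15298.5 that neutrophils with the same S100a8 and S100a9 UMIs would bring, judged from 13 cells named neutrophils when that library was clustered on its own. A weaker exposure of the control library that lowered every response alike is argued against, since interferon-stimulated genes in suprabasal cells differed by a median log2 ratio of 0.3081 alone. With cells of both libraries matched for UMIs the median log2 ratio of alarmins was 5.925 in suprabasal cells (99 per library) and 1.74 in basal cells (361 per library), so depth and the UMI minimum are argued against too. A genotype effect, a different time course or strength of the later response, and variation between mice may each explain the difference and were not separated.

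H2-Eb1 was lower in macrophages outside the control untreated library, at 3684 CPM there and 458.3, 120.9 and 145.3 CPM in control imiquimod, labelled-null untreated and labelled-null imiquimod. A lower class II programme is argued against: in untreated skin the other 6 MHC class II genes had a median log2 ratio of 0.1025 where H2-Eb1 had -4.92. A donor variant of H2-Eb1 or its region may be the source. In Langerhans-like cells of the labelled-null imiquimod library H2-Eb1 UMIs came to 2.58 (2.31 to 2.88) per 100 H2-Ab1 UMIs, against 35.0 (30.8 to 39.8) in control untreated, so a second cell type also had less. CD1 mice are outbred, and no genotype at this locus is given in the sources used here, so the variant itself was not seen.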

How the results depend on the processing

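The alternatives with joint clusters alone and with cells of at least 3100 UMIs were chosen after the data had been seen; the others were planned. Of the list medians under all alternatives, 2813 stayed within their counting interval, 234 moved and 17 changed sign. Of the named genes 2977 stayed, 554 moved and 19 changed sign. Counts of listed genes stayed within 1.5 times in 315 cases and moved in 57, class shares stayed in 101 and moved in 22, and correlations across genes stayed in 28 and moved in 18. These ranged from 0.183 to 0.419 in basal keratinocytes, 0.341 to 0.54 in suprabasal keratinocytes, 0.353 to 0.443 in the fibroblast class and 0.386 to 0.588 in macrophages. No sign of a called value changed with TMM factors, 5 counts added, the mean over cells, at least 100 UMIs or cells of at least 3100 UMIs. Every kept cell had over 1000 UMIs, so the share among such cells moved nothing. At Leiden resolution 0.5 there was no macrophage or monocyte class to compare. With each library clustered on its own there was none in labelled-null imiquimod, so its macrophage values were not checked at either setting. The values given next are those that changed sign, and those of counts, shares and Ovol1 that moved. Except where a lower depth or fewer measured genes are named, the cause was not tested.

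With at least 500 genes and at most 5% mitochondrial UMIs, Lcn2 in basal keratinocytes (control imiquimod over control untreated) went to -1.23 and Lor in suprabasal keratinocytes to 0.512. In control untreated, control imiquimod and labelled-null untreated, all epithelial classes held 30.5%, 48.5% and 50.9% of cells, the fibroblast class 57.6%, 45.7% and 40.6%, and the T or NK cell class 3.80% in labelled-null imiquimod. An Ovol1 UMI was seen in 16.1%, 31.7% and 26.3% of suprabasal keratinocytes of these 3. The cause was not tested.

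With called doublets kept, control imiquimod over control untreated had 38 listed genes lower in suprabasal keratinocytes, and Krt17 there went to -0.1. For labelled-null imiquimod over untreated, 45 were lower in basal keratinocytes and the immediate early and dissociation median in suprabasal keratinocytes went to -0.611. For labelled-null over control untreated, 26 were higher and 7 lower in basal keratinocytes and 21 lower in suprabasal keratinocytes, where Krt16 went to -0.333 and Krt17 to -0.831. For labelled-null over control imiquimod, 42 were lower in basal keratinocytes, where the medians of other chemokines went to 0.373, immediate early and dissociation to 0.133 and differentiation keratins to 0.452, and in suprabasal keratinocytes immediate early and dissociation went to -0.408. Labelled-null imiquimod held 54.8% fibroblast and 3.95% T or NK cell members, and 15.4% of suprabasal keratinocytes of control untreated had an Ovol1 UMI. The cause was not tested.

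At Leiden resolution 0.5 Lor in suprabasal keratinocytes (control imiquimod over untreated) went to 0.207, and for labelled-null over control untreated 8 listed genes were lower there and Krt16 went to -0.511. The T or NK cell share in labelled-null imiquimod was 3.76%, and 15.0% and 24.4% of suprabasal keratinocytes of control untreated and control imiquimod had an Ovol1 UMI. At Leiden resolution 2, 34 listed genes were lower in suprabasal keratinocytes for control imiquimod over untreated and 8 for labelled-null over control untreated, where Krt16 went to -0.283, and the T or NK cell share was 3.74%. The cause was not tested.

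With each library clustered on its own, control imiquimod over untreated in basal keratinocytes had activation keratins and Krt6a at -0.225 and Lcn2 at -1.74, and in suprabasal keratinocytes 40 listed genes lower and Ovol1 at -0.278. The immediate early and dissociation median of labelled-null imiquimod over untreated in suprabasal keratinocytes went to -0.0639. For labelled-null over control untreated 56 were lower in basal keratinocytes, 47 higher and 8 lower in suprabasal keratinocytes, and Krt16 there went to -0.579. For labelled-null over control imiquimod in basal keratinocytes 52 were lower, aryl hydrocarbon receptor targets went to 0.104, immediate early and dissociation to 0.256, differentiation keratins to 0.715 and Mki67 to -0.00138. Shares of the fibroblast class were 35.5% and 54.1% in labelled-null untreated and imiquimod, and the T or NK cell share 3.79% in the latter. The cause was not tested.

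Thinning to 1000 UMIs leaves fewer UMIs and so fewer measured genes, which lowers the counts by construction. For control imiquimod over untreated the listed genes higher and lower were 43 and 33 in basal keratinocyte, 33 and 11 in suprabasal keratinocyte and 26 and 27 in macrophage or monocyte classes, and Lor in basal keratinocytes went to 0.491. For labelled-null imiquimod over untreated they were 73 and 46, 67 and 22, and 31 and 32 in that order, with 51 lower in the fibroblast class. For labelled-null over control untreated they were 8 and 6, 11 and 0, and 14 and 22, with 32 higher in fibroblasts. For labelled-null over control imiquimod they were 63 and 48, 68 and 17, and 17 and 15, with 52 lower in fibroblasts and the median of differentiation keratins in suprabasal keratinocytes at 0.0673. The Ovol1 shares of suprabasal keratinocytes became 2.26%, 2.89%, 4.36% and 17.6%.

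With list members of at least 100 UMIs fewer genes were measured, which lowers counts by construction. In the macrophage or monocyte class 33 were higher for control imiquimod over untreated, 43 higher and 30 lower for labelled-null imiquimod over untreated, 23 higher for labelled-null over control untreated and 27 higher and 14 lower for labelled-null over control imiquimod. Labelled-null over control untreated had 6 higher and 6 lower in the basal keratinocyte, 17 higher and 3 lower in the suprabasal keratinocyte and 37 higher in the fibroblast class, and labelled-null over control imiquimod 26 lower in the suprabasal keratinocyte class.

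With joint clusters alone, the labelled-null imiquimod library kept 122 basal and 63 suprabasal keratinocytes. Over labelled-null untreated, basal keratinocytes had 72 listed genes higher, cornified envelope at -1.46, barrier lipid synthesis at -0.834 and Cldn1 at 0.898, and suprabasal keratinocytes 64 higher, IL-1 family at -0.0635, immediate early and dissociation at -0.163 and Krt17 at -0.26. Over control imiquimod, basal keratinocytes had 70 higher, cornified envelope at -1.25, barrier lipid synthesis at -0.425, Il1b at -0.416 and Cldn1 at 0.0983, and suprabasal keratinocytes 50 higher and Krt17 at -0.73. In that library all epithelial classes held 13.1% and fibroblasts 52.3% of cells, and 55.6% of suprabasal keratinocytes had an Ovol1 UMI. The shares differ because the cells of unnamed clusters then have no class. For the genes the cause was not tested, but 82 of the 122 basal cells kept were in cluster 10. Cluster 3 had been left unnamed because S100a8 and S100a9 are neutrophil markers, so this alternative leaves out cells by their alarmins. The cells that the joint clustering left unnamed were led by S100a8, S100a9 and Krt16, so keratinocyte values of this library rest on the choice of class source.

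With cells of at least 3100 UMIs, all epithelial classes held 55.0% and 56.3% in control imiquimod and labelled-null untreated, fibroblasts 58.0% in control untreated and the T or NK cell class 1.77%, 0.467% and 0.601% in control untreated, control imiquimod and labelled-null untreated. T or NK cells are shallow, so the UMI minimum of the labelled-null imiquimod library limits what its shares can be set against. Depth also limits Il1a, Flg and Flg2, whose UMIs in suprabasal keratinocytes were 12 or fewer in each library.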

Other observations

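No test of an explanation was run for the values given here, and they were picked out after their values had been seen.

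Cell types with few cells also differed between libraries. Langerhans-like cells numbered 9, 13, 6 and 92 in control untreated, control imiquimod, labelled-null untreated and labelled-null imiquimod, and mural cells 106, 66, 84 and 232. A joint cluster of T or NK cells led by Il17a held 151 cells, of which 138 were from labelled-null imiquimod. Il17a in T or NK cells stood at 1461, 3454, 2142 and 7013 CPM in that order. In mural cells the immediate early and dissociation list had 15 of 18 members lower under imiquimod in the control pair (median -1.18) and 2 higher and 3 lower in the labelled-null pair (median -0.09).

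Upper hair follicle keratinocytes were also compared. Interferon-stimulated genes were higher under imiquimod for 15 of 15 members in the control pair (median 5.41 [4.68]) and 17 of 17 in the labelled-null pair (median 5.84 [4.38]). The medians of alarmins and antimicrobial proteins were 4.26 [2.95] and 6.38, and those of cholesterol synthesis 0.22 and 2.41.

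Some transcripts differed by library in keratinocytes, fibroblasts and macrophages alike. In basal keratinocytes Tpm3-rs7 stood at 45.2 CPM in control untreated and 6.74, 8.90 and 7.20 in control imiquimod, labelled-null untreated and labelled-null imiquimod, and it was also highest in control untreated in fibroblasts, at 42.8 CPM against 3.82 to 4.03. Baiap2l1 stood at 217.5 CPM in basal cells of labelled-null untreated and 19.6, 14.4 and 9.41 in control untreated, control imiquimod and labelled-null imiquimod. In basal cells Rps26-ps1 stood at 205.4, 1195, 806.6 and 305.9 CPM in control untreated, control imiquimod, labelled-null untreated and labelled-null imiquimod and AY036118 at 17.1, 53.2, 78.9 and 19.0 CPM. With 1 library per group, mouse and group cannot be separated for these genes. Hba-a1 in fibroblasts stood at 3.89, 0.669, 5.01 and 105.2 CPM.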
